A study of Rattus norvegicus with 4 samples.

How the data were processed

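NR8383 is a macrophage line established from rat lung lavage, and the labels describe cells taken after 20 passages and grown submerged in medium with 15% serum and 2 mM glutamine. All 4 samples belong to 1 group, the submerged control, and the series' design text calls them biological replicates. No second condition was analysed here, so no comparison between conditions was made. The labels give different times: the design text gives 4 h of submerged incubation and the treatment protocol gives 48 h after seeding. Whether these are separate intervals or conflict was not settled here, and values are reported for the group without a duration.

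RNA was labelled with Cy3 and hybridised to one-colour Agilent rat arrays, per the labels' protocols, from 100 ng of RNA that had passed an integrity minimum of 7.5. The arrays were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. The deposited values used were fluorescence intensity per spot: the processed signal, which the software had already background-corrected, and the mean and local background signals, all on a linear scale and not normalized between arrays, per the file headers. The software's detection and outlier flags were used as deposited. All 4 arrays lay on 1 slide and were scanned together, so no slide or scan batch could be tested. The number of arrays limits the precision of every value.

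Each array held 62976 spots, of which 58717 were not controls, for 45598 different probes. No spot was saturated. Spots flagged as non-uniform or as population outliers were left out. The log2 processed signal minus the array's 75th percentile over non-control spots was taken as the level, and spots of a probe were averaged. A probe was called detected on an array when over 0.5 of its unflagged spots were well above background, and a gene when at least 1 of its probes was detected on all 4 arrays. The level of a gene is that of its brightest detected probe, or of its brightest probe where none was detected. A call can therefore rest on 1 of several probes, such as 1 of 2 for Csf1r, Abca1, Nod2, Arnt and Foxj1. Lack of detection can likewise rest on 1 probe, as for Gclm, Cd74, Marco, Il6, Scd, Spp1 and Ahr. Whether such a probe had failed was not tested. Levels of different probes are not comparable, and none are ranked.

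Probe names came from the files. Accessions were matched without version to a RefSeq gene table of GRCr8, used for names alone: 23863 probes were named by accession, 5124 by symbol and 351 by an older symbol, and 16260 kept the array's name. This gave 18893 genes with a symbol. Coordinates are those of the files, on rn4, and no exon or UTR annotation was used.

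Before the data were examined, 24 pathway lists and 12 lists of markers of other cell types were fixed. Of 498 list memberships, 494 were on the array, and Itgax, Nlrc4, Stab1 and Siglech were not matched. The genes named in the text were also set by a fixed rule: the first 4 symbols of each list with a probe; the members of a list where 4 or fewer were detected or were not detected; any list member past the variance test; and up to 20 genes of largest SD past that test. A gene named outside this rule was chosen after its values were seen; Itgam's result over several probes and the ribosomal Rn18s probe are such cases, as are further list members given as examples. Some genes that the rule names are not reported here.

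List detection was tested with a two-sided Fisher's exact test of each list against all other named genes, with Benjamini-Hochberg adjustment over 36 lists. Variance between replicates was tested with limma 3.58.1 in R 4.3.3: the residual variance of each probe detected on all arrays was set against a robust prior that follows mean signal (an F test, Benjamini-Hochberg at 0.05). Co-variation of a list was the SD over arrays of its mean level, set against 10000 random lists matched on signal in 10 classes, for lists with at least 5 detected members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

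The scripts were tested on simulated data. Among 19408 simulated probes on 4 arrays, the variance test called 0.5% of 200 probes whose SD was 4 times that of the others, 63.5% at 8 times and 92.0% at 16 times, with 0, 10 and 5 false calls. In 20 simulations with no such probe it made 0 calls. Fisher's test called 94.7% of lists of 20 set at 95 percent detection, with 0.08 false calls per simulation of 36 lists. The co-variation test called 100% of lists of 15 genes moved together by an SD of 0.3, with 0.3 false calls per simulation.

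Alternatives fixed in advance were another detection flag, detection on at least 2 arrays, all probes of a gene required, flagged spots kept, normexp background correction (offset 50), quantile normalization, the median of detected probes as scale, no filter on dim probes, a prior without the robust step or without the trend, a threshold of 0.01, unmatched random lists, list medians, and each replicate left out. A background without chemosensory receptors, scaling on 8 bright spike-in probes and a test on means over probes of a gene were added after seeing the data.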

Results

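The transcriptome of NR8383 cells, a rat alveolar macrophage line, was measured under submerged culture in 4 replicates on one-colour arrays. The 75th percentile of the processed signal was 1317, 1489, 1179 and 958 fluorescence units on replicates 1 to 4. On these arrays 11342, 11289, 10804 and 10649 of the 18893 named genes were detected. The series holds 1 group, so the question its design allows is which genes these cells express and how far replicate cultures differ. Levels below are log2 values relative to the array's 75th percentile, given as mean ± SD over 4 replicates.

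Of the named genes, 10350 (54.8%) were detected on all 4 arrays, 7135 on none and 1408 on 1 to 3. Across these 10350 genes, which are not independent replicates, Pearson's r between arrays lay between 0.9929 and 0.9972 over the 6 pairs. The closest pair, replicates 1 and 2, had an SD of log2 differences of 0.191, and the widest, replicates 3 and 4, of 0.303. The median SD of a gene's level was 0.11. Among 1029 detected probes printed on 10 spots, the median SD between arrays was 0.095, which was 5.72 times the standard error of a mean of 10 spots on 1 array. That standard error holds no labelling or hybridisation noise, so whether any arrays shared an RNA was not tested.

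**Figure D1:**
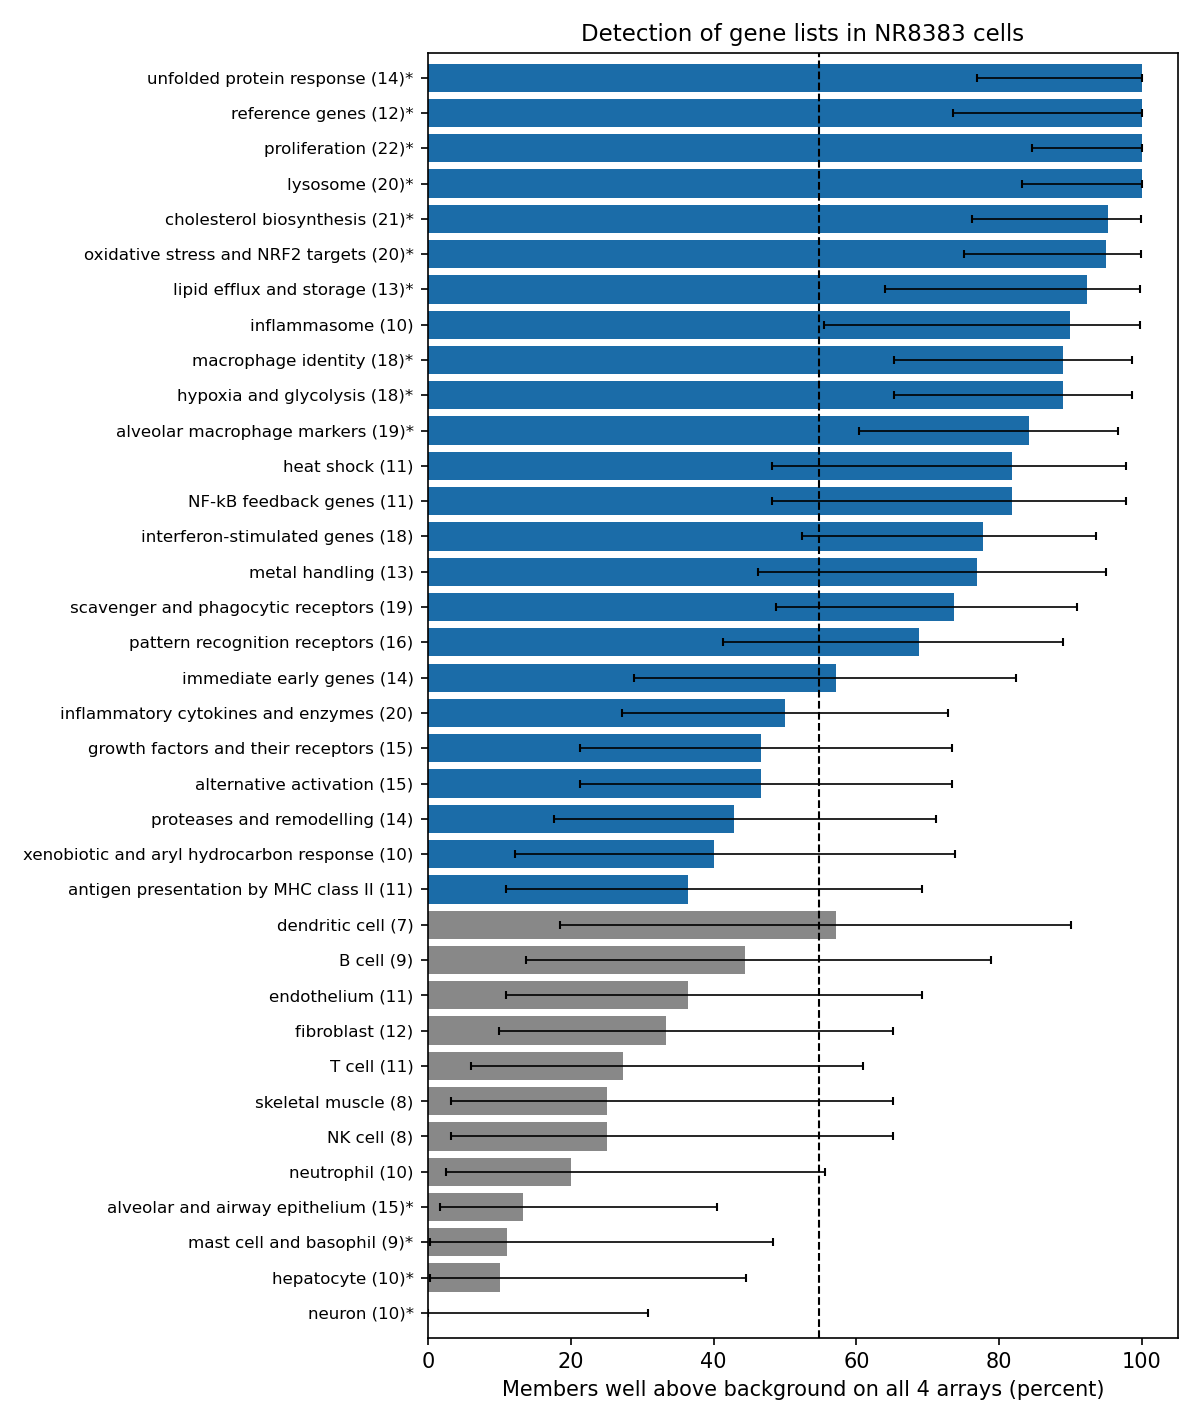
Percent of each list's members well above background on all 4 arrays (horizontal axis), for 24 pathway lists (blue) and 12 lists of markers of other cell types (grey), with the number of members on the array in brackets. Bars carry exact 95% binomial intervals over the members, asterisks mark lists past Fisher's exact test at an adjusted 0.05, and the dashed line is the 54.8% of all named genes; proliferation and lysosome lie at 100% and neuron at 0%.

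Macrophage genes were detected on all arrays. Cd68 lay at 4.74 ± 0.05, the growth factor receptor Csf1r at -0.02 ± 0.10, the transcription factor Spi1 at -0.43 ± 0.12 and the integrin Itgam at -0.90 ± 0.74. In the macrophage identity list 16 of 18 members were detected, and Adgre1 (F4/80) and the haemoglobin scavenger receptor Cd163 were not. Adgre1 passed on 1 array. The alveolar macrophage list had 16 of 19 members detected. Among them were the lipid-regulating nuclear receptor Pparg at 3.86 ± 0.19, the fatty acid carrier Fabp4 at -1.12 ± 0.30 and Siglec5 at -3.28 ± 0.20. The scavenger receptor Marco, the carbonic anhydrase Car4 and Chi3l1 were detected on no array. Both lists were detected more often than other genes in Fisher's exact test, with adjusted p of 0.012 and 0.028. The alveolar call was lost with the positive and significant flag (adjusted p = 0.20), with detection on at least 2 arrays (0.092) and against a background without chemosensory receptors (0.080).

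All 20 lysosomal genes were detected, among them the protease Ctsd at 6.71 ± 0.17, the membrane protein Lamp1 at 3.07 ± 0.10, the acid lipase Lipa at 2.64 ± 0.15 and the regulator Tfeb at -1.98 ± 0.05. Of 21 genes of cholesterol biosynthesis 20 were detected, including Hmgcs1 at 1.49 ± 0.30 and Sqle at 1.55 ± 0.01. The lipid efflux and storage list had 12 of 13 members detected, with Abca1 at -2.99 ± 0.16, Apoe at -4.43 ± 0.14, the lipid droplet protein Plin2 at 1.66 ± 0.11 and the lipase Lpl at 5.63 ± 0.13. Scd was detected on no array. The adjusted p of Fisher's exact test was 1.6e-04 for the lysosome, 9.4e-04 for cholesterol biosynthesis and 0.027 for lipid efflux. The last of these missed the threshold with the positive and significant flag (0.097), with at least 2 arrays (0.060) and without chemosensory receptors in the background (0.052).

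All 22 proliferation genes were detected. Mki67 lay at 3.14 ± 0.14, Top2a at 1.33 ± 0.15, Cdk1 at 3.55 ± 0.04 and Pcna at 2.40 ± 0.04. Oxidative stress genes and NRF2 targets were detected in 19 of 20 cases, with haem oxygenase Hmox1 at 3.46 ± 0.37, Nqo1 at -2.04 ± 0.09 and Srxn1 at 2.15 ± 0.04. Gclm, a subunit of the glutathione synthesis enzyme, was detected on no array by its 1 probe. The 14 unfolded protein response genes were all detected, including the chaperone Hspa5 at 3.06 ± 0.11, Ddit3 at 1.49 ± 0.12, Xbp1 at 1.37 ± 0.05 and Atf4 at 3.64 ± 0.08. In the hypoxia and glycolysis list 16 of 18 members were detected, with Hif1a at 1.05 ± 0.07, the glucose transporter Slc2a1 at 1.72 ± 0.25 and Ldha at 6.33 ± 0.09. Vegfa was detected on no array and Egln3 on 1. All 12 reference genes were detected, among them Actb at 6.37 ± 0.19, Gapdh at 6.32 ± 0.07, B2m at 5.78 ± 0.12 and Hprt1 at 3.29 ± 0.11. Fisher's exact test gave adjusted p of 8.9e-05 for proliferation, 1.3e-03 for oxidative stress, 1.7e-03 for the unfolded protein response, 4.1e-03 for the reference genes and 0.012 for hypoxia and glycolysis.

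Innate immune lists did not pass the detection test. Its simulation planted only lists of 20 at 95 percent detection. Shorter lists and smaller differences were not simulated, so a list that did not pass, here or below, may still differ from other genes. Of 20 inflammatory cytokines and enzymes 10 were detected, with Tnf at 0.92 ± 0.11 and Il1b at 2.47 ± 0.22, while Il6 was detected on no array and Nos2 on 2 (adjusted p = 0.72). The inflammasome list had 9 of 10 members detected, with Nlrp3 at -2.56 ± 0.25, Casp1 at 0.28 ± 0.06, Pycard at -0.19 ± 0.18 and Gsdmd at 2.19 ± 0.04, and Aim2 on 3 arrays (0.065). Interferon-stimulated genes were detected in 14 of 18 cases, with Irf7 at -1.80 ± 0.30, Isg15 at -1.49 ± 0.13 and Mx1 at -1.46 ± 0.20. Ifit1 and Rsad2 were detected on no array, Ifit3 on 1 and Ifih1 on 3 (0.12). NF-kB feedback genes gave 9 of 11, with Nfkbia at 0.11 ± 0.08, Tnfaip3 at -2.69 ± 0.16, Nfkb2 at 0.46 ± 0.09 and Relb at -0.29 ± 0.31, and neither Birc3 nor Traf1 was detected (0.22). Pattern recognition receptors gave 11 of 16, with Tlr2 at 0.94 ± 0.17, Tlr4 at -0.98 ± 0.29, Clec7a at 4.15 ± 0.01 and Nod2 at -3.12 ± 0.11 (0.41). Scavenger and phagocytic receptors gave 14 of 19, with Msr1 at -3.42 ± 0.19, Cd36 at 4.98 ± 0.06, Mertk at -4.18 ± 0.15 and Scarb1 at 1.13 ± 0.06 (0.21). The inflammasome list passed with detection on at least 2 arrays (0.029), with every probe of a gene required (0.025) and without replicate 4 (0.013). The interferon list passed with the positive and significant flag (0.034) and without replicate 3 (0.044), and the pattern recognition list with that flag (0.016).

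The list for antigen presentation by MHC class II had 4 of 11 members detected. These were RT1-Db1 at -3.18 ± 0.52, RT1-DMa at 2.28 ± 0.06, RT1-DMb at 2.00 ± 0.14 and the costimulatory receptor Cd40 at 2.73 ± 0.16. Cd40 rests on 1 of its 3 probes. The invariant chain Cd74, RT1-Da, RT1-Ba and the transactivator Ciita were detected on no array. Of 15 alternative activation genes 7 were detected, including Arg1 at -0.05 ± 0.27 and Mrc1 at 0.15 ± 0.27, while Chi3l3 and Retnla were not. The growth factor list also gave 7 of 15, with Tgfa detected at -2.12 ± 0.21 on 1 of its 3 probes, and Egfr, Csf1 and Csf2 not. Proteases and remodelling genes gave 6 of 14, with Mmp9 at -1.50 ± 0.40, Mmp12 at -1.40 ± 0.37 and Timp1 at -5.13 ± 0.52, and Spp1 on no array. Immediate early genes gave 8 of 14, with Jun at -0.18 ± 0.20 detected and Fos, Egr1 and Dusp1 on no array. Heat shock genes gave 9 of 11, with Hspa8 at 6.66 ± 0.05, Hsp90aa1 at 4.49 ± 0.02 and Dnajb1 at 0.17 ± 0.08, and the inducible Hspa1a and Hspa1b on no array. Metal handling genes gave 10 of 13, with the metallothioneins Mt1 at 2.53 ± 0.17 and Mt2A at -3.52 ± 0.24 and the transporter Slc11a1 at 1.26 ± 0.26, and neither the iron exporter Slc40a1 nor Mt3 on any array and Hamp on 3. The xenobiotic list gave 4 of 10, namely Arnt at -3.54 ± 0.15, Tiparp at -2.45 ± 0.09, Ugt1a6 at 2.60 ± 0.09 and Nqo1, while Cyp1a1, Ahr and Cyp1b1 were detected on no array. None of these lists passed Fisher's exact test, and their adjusted p lay between 0.22 and 1.

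Lists of markers of other cell types had between 0% and 57.1% of their members detected. No neuronal marker of 10 was detected, Snap25, Syt1, Rbfox3 and Gad1 among them (Fisher's exact test, adjusted p = 2.1e-03). Epithelial markers gave 2 of 15, Ager at -4.38 ± 0.12 and Foxj1 at -3.14 ± 0.17, while Sftpb and Epcam were detected on no array and Sftpc on 1 (5.8e-03). Hepatocyte markers gave 1 of 10, Ahsg at 1.24 ± 0.17 on 1 of its 2 probes, with Alb, Apoa1, Ttr and Cyp2e1 not detected (0.023). Mast cell and basophil markers gave 1 of 9, Hdc at -4.30 ± 0.44, with Kit and Fcer1a on no array and Cpa3 on 1 (0.036). Lists that did not pass the test were neutrophil (2 of 10, Mpo at -4.89 ± 0.30 and Camp at -1.06 ± 0.20, 0.11), T cell (3 of 11, Cd3d, Lck and Cd4, 0.15) and NK cell (2 of 8, Gzmb and Nkg7, 0.23). The same held for fibroblast (4 of 12, Col1a2, Dcn, Acta2 and Thy1, 0.23) and skeletal muscle (2 of 8, Acta1 and Tnni2, 0.23). Endothelium gave 4 of 11 (Cdh5, Pecam1, Vwf and Eng, 0.32), B cell 4 of 9 (Cd79a, Pax5, Fcrla and Cd22, 0.78) and dendritic cell 4 of 7 (Zbtb46, Clec9a, Batf3 and Cd83, 1). The epithelial call was lost with the positive and significant flag (60% detected, adjusted p = 0.91) and with at least 2 arrays (0.14). The mast cell call was lost under both of these (0.65 and 0.30), with every probe required (0.084) and without replicate 4 (0.10).

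The variance test called few genes. Of 19400 detected probes, 33 passed it in limma. In simulated data it called 0.5% of probes whose SD was 4 times that of the others, so the count does not show how many genes varied. A gene was called where its brightest detected probe passed, which gave 15 genes. Lcn2, which encodes the siderophore-binding protein lipocalin 2, lay at 2.06, 3.97, 1.57 and 4.37 on replicates 1 to 4, a 6.94-fold range (adjusted p = 0.013; probe on rn4 chromosome 3, 11511592 to 11511651). Cox6a2, a subunit of cytochrome c oxidase, spanned 4.16-fold (adjusted p = 0.045). Zfp7, Trpm8, Tmprss6, Wdr97, Thy1, Ermard, Kmt2d, C10h17orf58 and Sdccag8 were all lowest on replicate 3, with Zfp7 at -0.67, -0.98, -3.17 and 0.04. All of these genes also ranked the other replicates alike, with replicate 4 highest, then 1, then 2. Pcdh15, Or8b54c, Chst13 and the ribosomal RNA gene Rn5-8s were the others, and Rn5-8s lay at 1.76, 1.19, 3.10 and 3.13. Zfp7 rests on 1 of its 5 probes, Pcdh15 on 1 of 4, and Wdr97, Thy1 and Or8b54c on 1 of 2 each. The remaining probes of these genes were not detected on all 4 arrays. Other detected probes of Ermard, Kmt2d, C10h17orf58 and Sdccag8 did not share the drop on replicate 3 (deviations from -0.31 to 0.11). The count fell to 0 genes without the robust step, without the signal trend, with spike-in scaling and without replicate 3. It was also 0 at a threshold of 0.01, so the set is fragile. The count rose to 120 with normexp, 504 with no filter, and 34 and 23 without replicates 1 and 2. These last settings kept 14 of the 15 genes without replicate 1 and all 15 otherwise. On means over probes of the 2750 genes with at least 2 detected probes, a test chosen after seeing the data, 2 passed, Cox6a2 (4.23-fold range, adjusted p = 8.6e-04) and Itgam (2.65-fold, 9.3e-03).

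**Figure D2:**
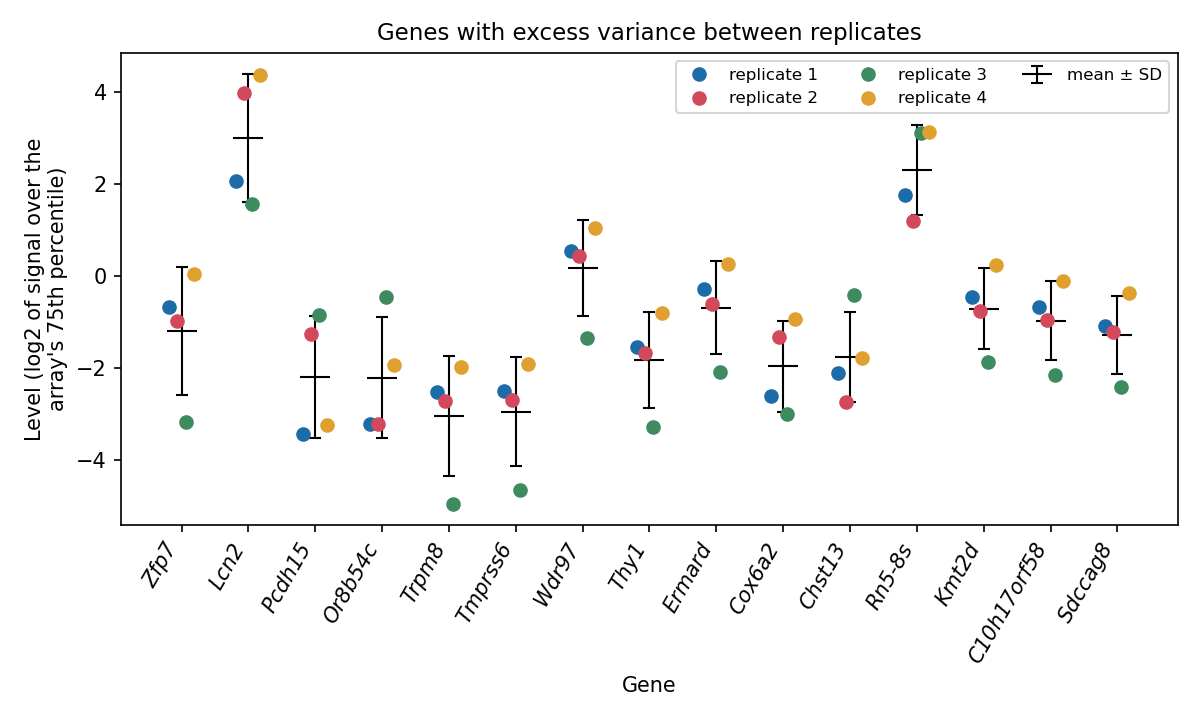
Level of the 15 genes past the variance test (vertical axis, log2 of signal over the array's 75th percentile) in each of the 4 replicates (coloured points), with mean and SD in black. Lcn2 lies at 3.97 and 4.37 in replicates 2 and 4 and at 2.06 and 1.57 in replicates 1 and 3, and 9 genes have a single low point in replicate 3. These 9 genes share 1 order of replicates, with 4 highest, then 1, 2 and 3.

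No list moved as a group between replicates past the threshold. Of 22 lists, 0 passed the random-list test after adjustment, and 3 had an unadjusted share below 0.05. These were alternative activation (SD of the list mean 0.21 over 7 detected members, adjusted 0.069), lysosome (0.089 over 20, adjusted 0.069) and proteases and remodelling (0.20 over 6, adjusted 0.076). The lysosome mean, centred on its own average, was -0.07, 0.05, -0.08 and 0.10 on replicates 1 to 4. The simulations planted an SD of 0.3, above the largest list SD seen here (0.21). How often smaller shifts would be called was not simulated. With the median of members in place of the mean, 4 lists passed: alternative activation (adjusted 2.2e-03), alveolar macrophage markers, lysosome and proteases (each 0.012).

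Spike-in control signal differed between arrays relative to the cells' own signal. The mean of 8 bright spike-in probes lay 1.87, 1.87, 2.46 and 2.86 log2 units above the 75th percentile on replicates 1 to 4. One Rn18s probe past the variance test lay at 3.83, 3.30, 5.07 and 4.71. Rn18s is not among the 15 genes because its brightest probe, at 8.08, 7.95, 8.27 and 8.49, did not pass (adjusted p = 0.73 in limma). Scaling on the spike-ins instead would shift replicate 4 against replicate 1 by 0.99 log2 units, so differences between replicates are stated relative to the 75th percentile.

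**Figure D3:**
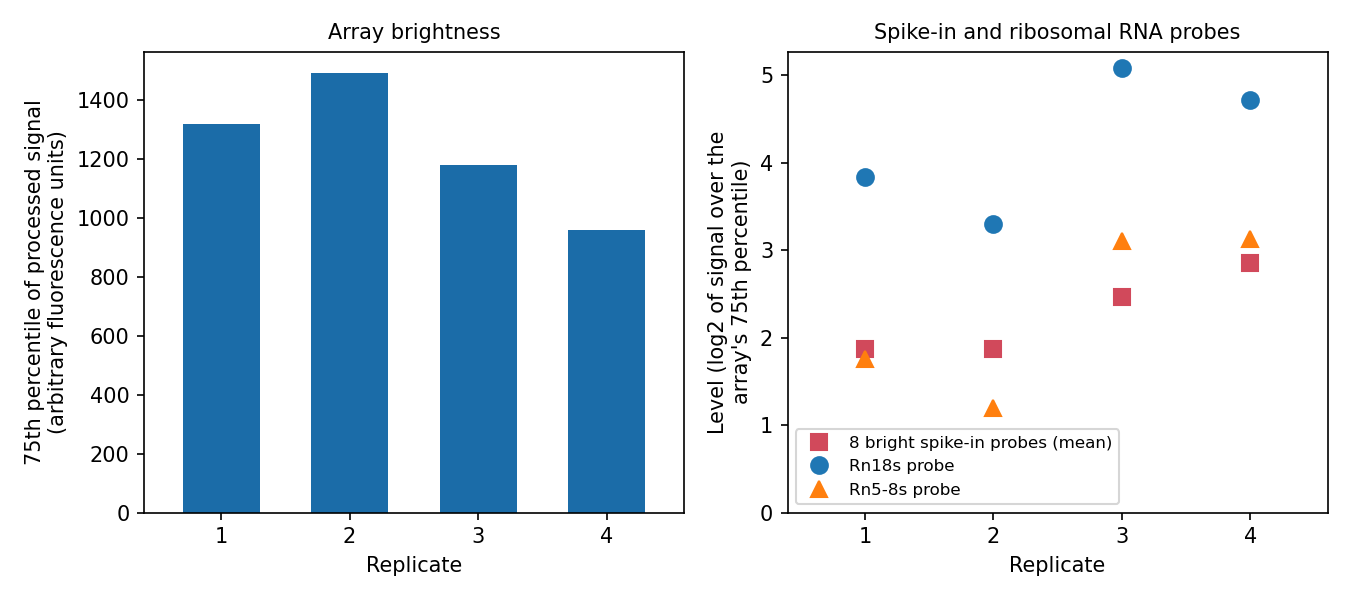
Left, the 75th percentile of processed signal per replicate (fluorescence units, bars from 0), from 958 to 1489. Right, the level (log2 of signal over that percentile) of 8 bright spike-in probes (mean) and of the Rn18s and Rn5-8s probes past the variance test, each point 1 array; all 3 are higher on replicates 3 and 4 than on replicates 1 and 2.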

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

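With 4 arrays, a sample stands apart when its gap to the nearest other, divided by the range, is over Dixon's 95% critical value, which chance gives in about 1 of 20 results. Of 150 results examined, 8 (5.33%) did so, against 7.5 expected by chance, and replicates 2, 3 and 4 stood apart in 2, 3 and 3 of them. Csf1r was lowest on replicate 2 (gap 0.902 of the range) and Clec9a highest there (0.872). Il1b was lowest on replicate 4, at 2.15 against 2.56 to 2.59 elsewhere (0.930), and Nfkb2 highest on it (0.893). On replicate 3 Col1a2 was lowest (0.833) and Gzmb highest (0.832). The mean of the NF-kB feedback list was lowest on replicate 3 (0.862, range 0.061 log2 units) and that of the unfolded protein response highest on replicate 4 (0.907, range 0.071).

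Outside the gene measurements, 2 of 96 control probes for external RNA were well above background on all 4 arrays. One had a mean signal of 30.7 and the other of 310 fluorescence units (309.7 ± 55.4, SD over 4 arrays), while the median of all 96 was 4.55. No source used here says whether such RNA was added.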

How the results depend on the processing

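No paired analysis was possible because the series holds 1 group. Spike-in scaling, the background without chemosensory receptors and the test on means over probes were chosen after seeing the data. The count of detected genes stayed within 1.5 times its value of 10350 with the other flag, with at least 2 arrays, with flagged spots kept and with every probe required, and was 10358 to 10568 with a replicate left out. Lists detected less often fell from 4 to 2 with the positive and significant flag and to 2 with at least 2 arrays, and numbered 3 to 4 without single replicates. Lists detected more often numbered 10 to 11 there. Lists that did not pass changed side of the other genes: growth factors (66.7%) and proteases (78.6%) with the positive and significant flag, proteases (64.3%) with at least 2 arrays, inflammatory genes (50.0%) and dendritic cell (28.6%) with every probe required, and immediate early genes (57.1%) and dendritic cell (57.1%) without chemosensory receptors.

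The variance result is the least stable. Against 15 genes, normexp gave 120, no filter on dim probes 504, and means over probes 2. The count was 0 without the robust step, 0 without the trend, 0 with spike-in scaling and 0 at a threshold of 0.01, and 0 to 34 with a replicate left out, the 0 being without replicate 3. In limma's main test 1261 probes had an unadjusted p below 0.05. Co-variation gave 4 lists with the median of members and 0 to 0 with a replicate left out. Median agreement between arrays was 0.9905 with no filter on dim probes, and 0.9939 to 0.9945 with a replicate left out. The cause of these changes was not tested. The variance test called few simulated probes at an SD 4 times that of the others, so smaller differences between cultures would mostly be missed. Signal near background limits the lists of dim markers.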

Other observations

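Several genes best known from other lineages were well above background on all 4 arrays. The B cell list included Cd22 at 2.83 ± 0.05, Fcrla at 1.33 ± 0.09 and the transcription factor Pax5 at -2.22 ± 0.29, while Ms4a1 and Cd79b were detected on no array. Vwf, known from endothelium, lay at 1.23 ± 0.27 with Kdr and Cldn5 undetected, and Ahsg, known from liver, at 1.24 ± 0.17 with Alb undetected. Cd22 rests on 1 of its 3 probes and Ahsg on 1 of its 2, the others not being detected on any array, while both Vwf probes were detected. Of 1448 chemosensory receptor genes, 75 (5.18%) were detected, against 58.9% of other genes. No source of their signal was tested.

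The tests below were chosen only after the result was seen, except those of neighbouring spots, neutrophils and single-probe faults; the division of the first pattern into parts was also made after its values were seen. The first pattern is the 23 probes past the variance test that were lowest on replicate 3, with a median deviation of -1.88 log2 units. Neighbouring detected spots, within 2 rows and columns, deviated by 0.026, which argues against damage at that scale. The 23 probes had a median column of 125 on arrays of 164 columns, and a wider positional effect was not tested. For 5 genes with other detected probes, Cox6a2 apart, those probes deviated by a median of 0.022, which argues against a difference in whole transcript levels for those genes. Both Cox6a2 probes (median deviation -1.35) had themselves passed the test and were nearly as low on replicate 1, so they decide nothing. For 16 probes there was nothing to compare: the gene had no other detected probe, or the probe had no gene symbol. Only 13 of the 23 probes had a gene symbol. The median C and T share, 55.0% against 50.0% for all detected probes, lay at the 98.6th percentile of random sets. Cross-hybridisation of a pyrimidine-matching RNA stays open as a candidate explanation and is not shown, since the bias was noticed in these same probes before it was tested. An isoform-specific change stays open. Zfp7, Trpm8, Tmprss6, Wdr97, Thy1, Ermard, Kmt2d, C10h17orf58 and Sdccag8 ranked all replicates in the same order. Whether their probes carried 1 shared signal was not tested.

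The second pattern is Lcn2, higher on replicates 2 and 4. Neutrophils in the cultures would bring their abundant transcripts, yet only 2 of 10 neutrophil markers were detected on all arrays, S100a8 on 3 arrays and S100a9 on none, which argues against them as the main source. The labels also describe a macrophage line after 20 passages, which argues against neutrophils in the cultures at all. Even so, S100a8, at -5.38, -5.02, -6.36 and -4.85 on replicates 1 to 4, was highest on replicates 2 and 4 like Lcn2. So were Camp, at -1.11, -0.98, -1.30 and -0.83, and S100a9 near background. Whether the line itself expressed these genes was not tested. A fault of its single probe cannot be told apart from a difference between cultures. The test used sibling probes of other genes, and Lcn2 has 1 probe, so the test could not decide the question for Lcn2. Across 2750 genes, sibling probes' deviations correlated at 0.21 in replicate 2 and 0.35 in replicate 4. Only the second passed the 0.3 that had been asked of both. Cox6a2 and the 3 Itgam probes were higher on the same replicates. Other list members were too, such as Ctsl (-2.03, -1.47, -2.15 and -1.22) and Mmp12 (-1.74, -1.22, -1.67 and -0.97). Cxcl10, at 1.27, 0.65, 1.46 and 0.58, went the other way, and genes of either kind were not counted. The lysosome and alveolar macrophage list means were also higher on replicates 2 and 4. That of the inflammasome list was lowest on replicate 4, and no list mean passed the co-variation test. Apart from neutrophils, no biological explanation was tested, since all replicates belong to 1 group.

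Spike-in signal and that of 2 ribosomal probes was higher on replicates 3 and 4 relative to the 75th percentile. The spike-in level spanned 0.99 log2 units over the arrays, and the mean of the Rn18s and Rn5-8s probes, chosen because they passed the variance test, spanned 1.84. The brightest Rn18s probe, which did not pass (adjusted p = 0.73), spanned 0.55, so 1.84 is not the size of a change in ribosomal RNA. No explanation was tested on values other than those that showed it.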
